A study of Mus musculus with 11 samples.

How the data were processed

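RNA of NSC34 cells, a mouse hybrid line of neuroblastoma and spinal cord cells with motor neuron features, was measured on 11 Affymetrix whole-transcript arrays. Per the labels' protocols, the cells were transfected with a hairpin vector, and stable clones were taken after puromycin selection. The groups were 4 arrays with a hairpin against Tardbp (shTardbp 1 to 4), 4 with a control hairpin against GFP (shGFP 1, 2, 3 and 5) and 3 with a control hairpin against Renilla luciferase (shLuciferase 1, 2 and 4). The labels do not say whether the arrays of a group came from separate clones or cultures, so the p-values measure only the spread between these samples, which may be technical.

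The deposited values are log2 expression values of probe sets, and Partek and RMA are named for them per the submitters' processing notes, with no version given. Background correction, normalization settings and the annotation build are not given in the sources used here. The table held 194293 probe sets. The platform annotation gave 179496 of them 1 gene symbol, 1328 several and 13469 none, and genes were named only from the first kind. These made 15803 genes with a median of 9 probe sets (at most 115), and 807 genes had 1 probe set. Symbols are those of the platform annotation, some of them old. Of them, 13727 were found as current symbols in the RefSeq gene table of the GRCm38.p6 assembly. The gene table served only for names and for which genes neighbour each other, because the probe sets' build is not stated. All per-sample columns were used.

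A gene's value was the mean of the log2 values of its probe sets. One linear model with 3 groups was fitted to all genes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with no filter on low values and no detection calls. Arrays were not paired by replicate number in this model. The contrasts were shTardbp minus the mean of the 2 control group means, shTardbp minus each control group, and shGFP minus shLuciferase. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Errors given with a log2 change are standard errors (SE) from this model. Tardbp was also tested by an exact two-sided permutation test of the 4 shTardbp against the 7 control arrays.

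Probe set usage means the change of a probe set relative to the other probe sets of its gene. It was tested with limma's diffSplice on probe sets above the 25th percentile of mean level, in genes above the median level with at least 3 such probe sets, with Simes-adjusted p-values per gene. This left 101898 probe sets in 7531 genes. Probe set positions were not used here, so a probe set cannot be assigned to an exon.

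Gene lists were fixed before the data were examined: core spliceosome, splicing regulators, TDP-43 splicing targets from earlier work, long neuronal genes, ALS-linked genes, motor neuron and neuronal differentiation markers, synaptic genes, cell cycle, interferon response, unfolded protein and integrated stress response, p53 targets, oxidative stress response, heat shock response, cholesterol synthesis, autophagy and lysosome, nuclear transport, mitochondrial oxidative phosphorylation, and markers of other cells (glia and Schwann cells; fibroblast and mesenchyme; muscle, epithelium and endothelium). The 20 lists share some genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and with fry. List counts are given over all genes tested and adjusted over the list alone.

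The genes named in the text were chosen by a rule fixed before the data were examined. It took Tardbp, the 10 largest rises and 10 largest falls in shTardbp among genes past the threshold whose 4 shTardbp values lay on one side of all 7 control values (leaving out unnamed clones, predicted genes and Riken cDNAs), up to 4 members of each list with the smallest adjusted p, and the 5 largest differences in each direction between the control groups. For usage it took 10 probe sets with the largest difference, 1 per gene, and up to 5 members of the list of TDP-43 targets. Other names were chosen after their values were seen, as stated there.

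The tests were run first on simulated probe set values with the real means and spreads, for shTardbp against both controls over 15803 genes. Of 50 genes raised by 1 on the log2 scale 50 were found, and 49 of 50 lowered by 1. At 0.5, 41 of 50 raised and 40 of 50 lowered genes were found, with 11 false calls among 15403 unchanged genes. For usage over 101898 probe sets, diffSplice found 180 of 200 probe sets shifted by 1 but also called 261 of 97566 in genes with no simulated usage change, more than the threshold allows. A test with a variance of its own for each probe set, added after that and after the real data were seen, found 158 of the 200 with 9 false calls among 168.

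Alternatives tried were the median of the probe sets, only genes above the median level, quantile normalization again, centring each array on its median, an intensity trend with robust eBayes, array weights, the replicate number as a block, each array left out in turn, pooled controls, pairwise fits, a minimum change of 0.5, other filters for usage and other list tests. The letter that opens the array code in the sample descriptions (C or P) as a block, a regional correction and the other usage test were added after seeing the data. No 2 arrays were copies: the smallest mean absolute log2 difference between any 2 was 0.227. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.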

Results

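The arrays measured transcript levels in stable NSC34 lines that carried a hairpin against Tardbp, the gene of the RNA-binding protein TDP-43, or a control hairpin. TDP-43 is a nuclear regulator of splicing that is lost from motor neuron nuclei in amyotrophic lateral sclerosis (ALS), and the series asks what its depletion does to transcripts and splicing in a motor-neuron-like cell. The 3 groups held 4 shTardbp, 4 shGFP and 3 shLuciferase arrays. Array medians ran from 6.82 to 6.92 on the log2 scale. In a principal component analysis of gene values, the first component held 46.2% of the variance and placed the shTardbp arrays at 22.6 to 24.5 and the controls at -16.7 to -12.3. The second component (18.5%) parted shGFP from shLuciferase. The third (9.18%) set shLuciferase 4 at 17.0, away from shLuciferase 1 (-7.61) and shLuciferase 2 (-9.43).

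Tardbp itself was lower in all 4 shTardbp arrays than in all 7 control arrays. Its gene value was 8.88 ± 0.0897 (SD, n = 4) in shTardbp, 9.28 ± 0.146 (n = 4) in shGFP and 9.29 ± 0.0869 (n = 3) in shLuciferase. The log2 change was -0.40 (SE 0.0722, limma adjusted p = 0.000713), or 75.8% of the control signal on the arrays (95% confidence interval 68.0 to 84.4). With the median of the probe sets it was -0.53 (limma adjusted p = 0.00426), so the share of transcript that remained depends on how probe sets are combined. The exact two-sided permutation test gave p = 0.00303, the smallest value that 330 splits allow. All 10 Tardbp probe sets were lower, by log2 differences from -0.175 to -0.573. The shTardbp arrays and shLuciferase 4 carry array codes that open with P and the other arrays codes that open with C, and what the letters mean is not given. With the letter as a block the change was -0.29 and the call was lost (adjusted p = 0.173, the highest of all alternatives, which began at 0.000221). Within the P arrays, all 4 shTardbp values lay below the 9.20 of shLuciferase 4.

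**Figure D1:**
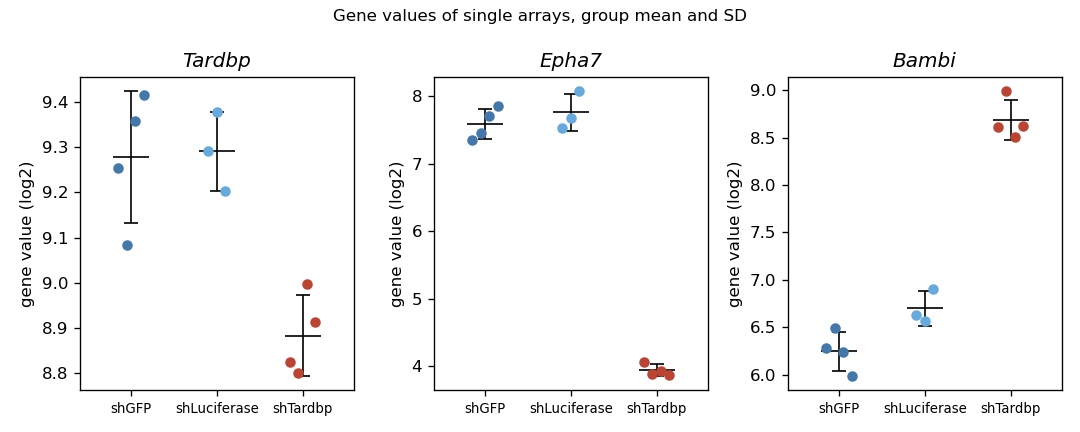
Gene values (log2, mean of a gene's probe sets) of Tardbp, Epha7 and Bambi in each array, with points for arrays and lines for the group mean and SD (shGFP n = 4, shLuciferase n = 3, shTardbp n = 4). Each vertical axis has its own range and does not start at 0. The 4 shTardbp arrays lie below all 7 controls for Tardbp and Epha7 and above them for Bambi.

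The first comparison asked which genes differed between Tardbp-depleted cells and both controls. Epha7, a receptor for ephrins, had the largest fall of the named genes (log2 change -3.74, SE 0.110, adjusted p = 2.01e-10, n = 4 against 7). Large falls were also seen for Fam19a1 (log2 -2.48, SE 0.0939), the endoplasmic reticulum peroxidase Gpx8 (-2.36, SE 0.0892), the orphan receptor Gprc5b (-2.22, SE 0.0895), Lrrc17 (-2.21, SE 0.0699) and the membrane metalloproteinase Mmp16 (-2.05, SE 0.0665). Gfra1, the co-receptor for the neurotrophic factor GDNF, fell 4.04-fold (-2.01, SE 0.0638), and Fam181b (-1.98), the matrix protein gene Prelp (-1.88) and the endocytic adaptor Eps15 (-1.81) fell as well. The Eps15 value averages probe sets that fell strongly with others that moved little, as described below. The controls of several of these genes differed, so the size of those falls depends on the control. Gfra1, Gprc5b and Eps15 were higher in shGFP than in shLuciferase, by 0.91, 0.75 and 0.53 on the log2 scale. The fall of Gfra1 was thus -2.47 against shGFP and -1.56 against shLuciferase. The gap between the controls was larger for Fam181b and Prelp. Fam181b was at 8.36 to 8.74 in shGFP, 6.64 to 6.94 in shLuciferase and 5.54 to 5.82 in shTardbp. Prelp was at 6.69 to 7.19, 5.64 to 6.08 and 4.44 to 4.61. The largest rises were those of Apol9b (4.82-fold, log2 2.27, SE 0.108), Bambi, a decoy receptor of the TGF-beta family (4.62-fold, 2.21, SE 0.109), the secreted neuronal protein gene Lgi1 (1.98, SE 0.101), the heparan sulfate sulfatase Sulf2 (1.93, SE 0.0613) and Cd74, the invariant chain of MHC class II (1.92, SE 0.0745). The calcium-activated potassium channel Kcnn3 (1.78), the olfactory receptor Olfr78 (1.78), the protocadherin Mupcdh (1.74), Dmkn (1.73) and the G protein subunit Gnb3 (1.71) followed. The size of several of these rises also depends on the control. Apol9b was at 4.66 to 5.24 in shGFP, 6.23 to 6.40 in shLuciferase and 7.65 to 7.99 in shTardbp. Sulf2 was at 7.21 to 7.43, 6.10 to 6.29 and 8.63 to 8.76. Adjusted p-values for these 20 genes were at most 8.63e-08. In each gene all 4 shTardbp arrays lay on the same side of all 7 controls, which the rule that chose them required. The shTardbp means of Epha7 (3.94), Gpx8 (4.41) and Mmp16 (4.02) lay below the 25th percentile of probe set values on every array (4.46 to 4.57), so they are not shown to be above background and the exact size of these falls is not known.

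In total 4825 of 15803 genes (30.5%) passed the threshold, 2141 higher and 2684 lower in shTardbp, with 63 of them at least 2-fold higher and 99 at least 2-fold lower. The median absolute log2 change of these genes was 0.369. Over all 15803 genes the 4 shTardbp values lay apart from all 7 control values in 2887, where chance would part 0.606%, and 2832 of these passed. With the array code letter as a block 2509 genes passed, and 22 of the named genes lost their call (Tardbp, Hspa1a, Snrpa1, Crem, Ift81, Nlgn2, Sesn2, Btg2, Cat, Gstm1, Dnajb4, Hsf1, Bag3, Hsd17b7, Lss, Rcc1, Nup188, Ndufa10, Uqcrfs1, Atp5o, Mbp and Pdgfrb, adjusted p = 0.0508 to 0.764). In all, 1345 passed with an absolute log2 change of at least 0.5.

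Against each control on its own, 4416 genes passed for shGFP and 4120 for shLuciferase. Epha7 fell against shGFP and against shLuciferase alike (adjusted p = 4.39e-10 and 9.09e-10), as did Lrrc17 (4.39e-10 and 2.26e-09), and Kcnn3 rose against both (7.87e-08 and 8.55e-08). In all, 1215 genes were higher and 1484 lower against both controls, 2699 together, and 77 passed in opposite directions. Independent lists of these sizes would share 231 higher and 351 lower genes, and simulated groups with no effect that shared the shTardbp arrays gave 0, which is chance with no effect and no baseline for comparisons that hold effects. With the shTardbp arrays divided so that each control was set against 2 of them, the overlap was 1491 to 1639 (652 to 729 higher and 830 to 910 lower, where independent lists would share 94.5 to 129 and 149 to 194). With the array code letter as a block 1933 genes passed against shGFP and 1418 against each control, and with the median of the probe sets 1776 passed against each control.

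**Figure D2:**
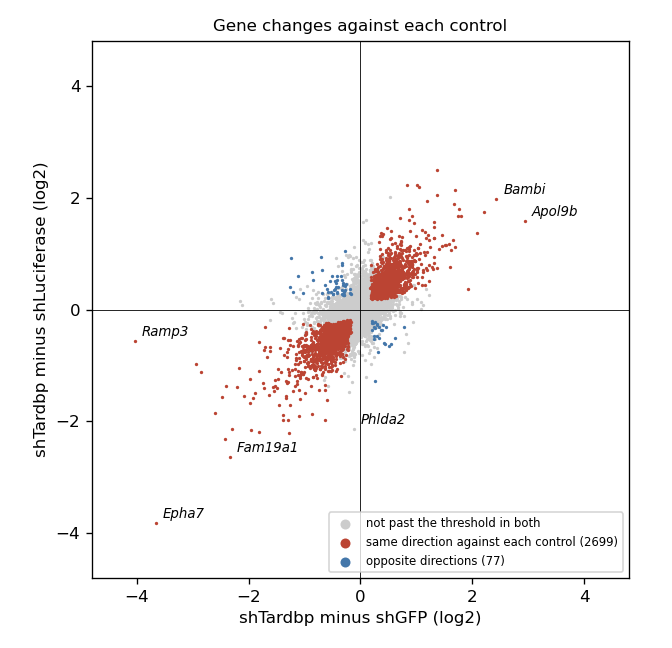
Log2 change of every gene in shTardbp against shGFP (horizontal) and against shLuciferase (vertical), 1 point per gene. Red points are the 2699 genes past the threshold against each control in the same direction, blue points the 77 in opposite directions, and grey points all others.

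Cell cycle genes fell together. Of 50 measured, 43 were lower and 1 higher in shTardbp (45 and 1 adjusted over the list alone), with a median log2 change of -0.55. Hmmr and Ndc80, which act in mitosis, fell 2.06-fold and 2.04-fold (log2 -1.04, SE 0.0774, and -1.03, SE 0.0734), and the transcription factor E2f8 and the replication factor Cdc45l fell 1.77-fold and 1.76-fold. The list test gave an adjusted p of 9.15e-23, and it was the only one of the 20 lists still past the threshold with an estimated correlation (adjusted p = 0.00342 with an estimated correlation). Between the controls 1 cell cycle gene was higher and 2 lower in shGFP. Without shLuciferase 4 the counts were 44 lower and 2 higher.

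In the core spliceosome list 20 of 57 measured genes fell, 3 rose and the other 34 did not pass (24 and 3 adjusted over the list alone; list test adjusted p = 0.00314, adjusted p = 0.392 with an estimated correlation). Prpf31, a factor of the tri-snRNP, and the Lsm ring protein gene Lsm3 fell 1.69-fold and 1.68-fold (log2 -0.75, SE 0.0527, and -0.75, SE 0.0870), while Sf3a2 and Snrpa1 of the U2 particle fell 1.34-fold and 1.42-fold. The same list was lower in shGFP than in shLuciferase (7 of 57 genes, adjusted p = 0.00366; adjusted p = 0.7 with an estimated correlation); against shLuciferase its test gave 0.000137 (adjusted p = 0.307 with an estimated correlation) and against shGFP 0.083. Over all alternatives the list's adjusted p ran from 0.000767 to 0.397 (the array code letter as a block), with 0.0555 over genes above the median level. Splicing regulators went both ways, 12 of 71 lower and 9 higher, with the same counts adjusted over the list alone. Elavl4 (log2 -0.53, SE 0.0584), Rbm10 (-0.83, SE 0.0940) and A2bp1, the older name of Rbfox1 (-0.81, SE 0.103), fell, and Brunol6, the older name of Celf6, rose (0.52, SE 0.0714). The list's median was 0.00991, its mean -0.0253 and its test pointed down with adjusted p = 0.718.

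Of 43 nuclear transport genes, 18 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 0.00114; adjusted p = 0.527 with an estimated correlation). The nuclear pore genes Nup85 (log2 -0.61, SE 0.0642) and Nup188 (-0.41, SE 0.0587), the Ran exchange factor Rcc1 (-0.52, SE 0.0704) and the importin Kpna6 (-0.44, SE 0.0594) were among them. Nup188 lies in a stretch of neighbouring genes of which 92 were lower and 9 higher in shTardbp, and Rcc1 and Kpna6 lie in another (Tmem68 to Pafah2) of which 241 were lower and 61 higher, with a median of -0.24. With the array code letter as a block this list's direction turned (adjusted p = 0.978, against 2.51e-05 as the lowest of the alternatives). Of 19 cholesterol synthesis genes, 9 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.01, adjusted p = 0.603 with an estimated correlation). Mvk, the mevalonate kinase, fell 1.89-fold (log2 -0.92, SE 0.0740), Hsd17b7 and Lss fell 1.32-fold and 1.23-fold (Lss with adjusted p = 0.109 against shLuciferase alone), and Tm7sf2 rose 1.48-fold. Its adjusted p was 0.398 with the array code letter as a block and 0.0968 over genes above the median level, and 0.00174 to 0.603 over all alternatives.

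Of 42 motor neuron and neuronal differentiation markers, 14 rose and 4 fell (17 and 4 adjusted over the list alone; adjusted p = 0.00158, adjusted p = 0.331 with an estimated correlation). The microtubule protein gene Mapt rose 1.77-fold (log2 0.83, SE 0.0768), and Syp and Chga, genes of synaptic and secretory vesicles, rose 1.61-fold and 1.57-fold, whereas the neuronal RNA-binding protein gene Elavl4 fell. Of 43 synaptic genes, 13 rose and 4 fell, the same counts adjusted over the list alone (adjusted p = 0.00994; adjusted p = 0.331 with an estimated correlation, 0.168 with the array code letter as a block, and 0.00105 to 0.331 over all alternatives). Sv2a, a synaptic vesicle protein gene, rose 2.09-fold (1.06, SE 0.0664) and Unc13a 1.67-fold (0.74, SE 0.0909, 1 probe set), while Unc13b fell (-0.73, SE 0.0551, to a mean of 4.24, not shown to be above background). Long neuronal genes divided into 7 higher and 6 lower of 37, with the same counts adjusted over the list alone. Astn2 (-0.78) and Cadps (-0.55) fell and Nlgn2 rose (0.44). Their median was 0.0101 and their mean -0.000207, and the test pointed up with adjusted p = 0.625.

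Of 36 autophagy and lysosome genes, 15 rose and 4 fell (18 and 4 adjusted over the list alone; adjusted p = 0.00382, adjusted p = 0.527 with an estimated correlation). Progranulin (Grn) rose 1.61-fold (log2 0.69, SE 0.0734), the lysosomal proteases Ctsd and Ctsb rose 1.60-fold and 1.53-fold, and the autophagy kinase Ulk2 rose 1.40-fold. The list passed against shLuciferase (adjusted p = 0.000202; adjusted p = 0.343 with an estimated correlation) and had adjusted p = 0.0696 against shGFP. Among 29 ALS-linked genes 9 rose and 5 fell, the same counts adjusted over the list alone (adjusted p = 0.222, and 0.0434 to 0.69 over the alternatives, the lowest with the array code letter as a block; adjusted p = 0.69 with an estimated correlation). Besides Grn and Unc13a, the motor protein gene Kif5a rose 1.70-fold, and Anxa11 fell (log2 -1.31, SE 0.0730, to a mean of 4.34, not shown to be above background). The list of TDP-43 splicing targets from earlier work, which includes Tardbp, had 10 higher and 4 lower of 25 genes (11 and 5 adjusted over the list alone; adjusted p = 0.0283, adjusted p = 0.331 with an estimated correlation). Madd (1.82-fold, log2 0.86, SE 0.0581), Mapt, Crem (0.56) and Ift81 (0.45) rose. This call was lost without shLuciferase 4 (adjusted p = 0.0666), without shTardbp 4 (0.0622), with array weights (0.0789) and over genes above the median level (0.138), in a range of 0.000469 to 0.331 over all alternatives. Against shGFP the list had adjusted p = 0.0612.

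**Figure D3:**
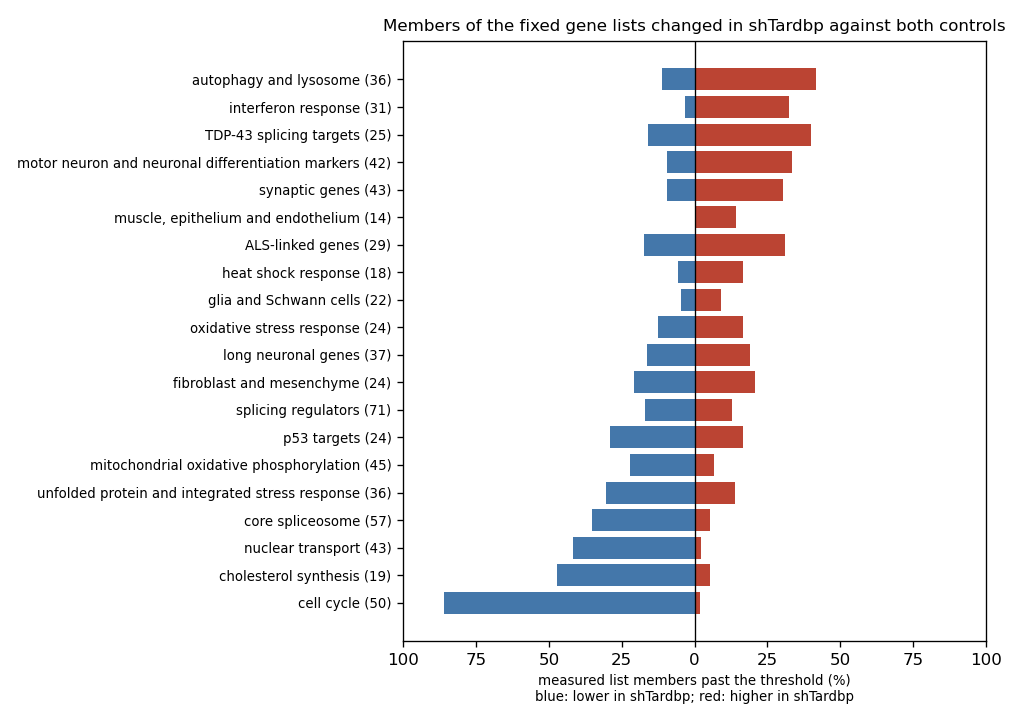
Share of the measured members of each fixed gene list (number measured in brackets) that passed the threshold in shTardbp against both controls, lower to the left in blue and higher to the right in red. Cell cycle stands at 43 lower and 1 higher of 50.

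The remaining lists did not pass the list test against both controls. Of 31 interferon response genes 10 rose and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 0.118), with Irf9 at log2 0.68 (SE 0.0720), Oasl1 at 0.57, Ddx58 at 0.58 and Ifi35 at 0.54; fry, which asks whether the genes move one way on balance, gave 0.000741, and over the 10 members above the median level camera gave 0.0346 (adjusted p = 0.331 with an estimated correlation over all members). Unfolded protein and integrated stress response genes had 5 higher and 11 lower of 36 (6 and 12 adjusted over the list alone; adjusted p = 0.19, 0.0107 with fry, and adjusted p = 0.74 with an estimated correlation). Atf3, a stress-induced transcription factor, fell 3.47-fold (-1.79, SE 0.0778), Myd116 and Xbp1 fell 1.80-fold and 1.33-fold (Xbp1 with adjusted p = 0.0655 after the shift of neighbouring genes was subtracted), and Sesn2 fell against shGFP (adjusted p = 1.55e-05) but had adjusted p = 0.863 against shLuciferase. Of 24 p53 targets 4 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.794). Ddb2 (0.57), Trp53inp1 (0.65, adjusted p = 0.0592 against shGFP alone) and Btg2 (0.58) rose, and Sesn2, which is also on this list, fell (-0.45). Oxidative stress genes stood at 4 higher and 3 lower of 24 (5 and 4 adjusted over the list alone; adjusted p = 0.336, and 0.0150 to 0.753 over the alternatives, the lowest with the array code letter as a block; adjusted p = 0.753 with an estimated correlation), where Gstm1 (0.76, 1 probe set), Ephx1 (0.49) and Fth1 (0.31) rose and Cat fell (-0.43). Heat shock genes stood at 3 higher and 1 lower of 18, the same adjusted over the list alone (adjusted p = 0.389). Dnajb4 rose (0.72) and Hsf1 fell (-0.28, adjusted p = 0.156 with the median of the probe sets); Bag3 (0.23) had adjusted p = 0.923 against shLuciferase alone and 0.145 after the shift of neighbouring genes was subtracted, and Hspa1a (0.24, adjusted p = 0.0329) lost its call when any of shGFP 1, 2 or 3, shLuciferase 1 or 2, or a shTardbp array was left out (0.0503 to 0.092), and its direction turned with the array code letter as a block (-0.062). Of 45 oxidative phosphorylation genes 10 fell and 3 rose (13 and 3 adjusted over the list alone; adjusted p = 0.117), among them Uqcrc1 (-0.34), Ndufa10 (-0.30), Uqcrfs1 (-0.43) and Atp5o (-0.59), which fell (the last 2 with adjusted p = 0.156 and 0.0805 with the median of the probe sets, and Atp5o with 0.0732 after the regional shift was subtracted); the list passed without shGFP 5 (0.0456) and without shTardbp 2 (0.0308; adjusted p = 0.753 with an estimated correlation over all arrays), and against shLuciferase alone (0.026; adjusted p = 0.659 with an estimated correlation) but not against shGFP (0.445).

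Markers of other cells showed no shift as lists. Glia and Schwann cell markers had 2 higher and 1 lower of 22 (the same adjusted over the list alone; adjusted p = 0.364). Pdgfra fell 1.89-fold, Erbb3 rose 1.48-fold, and Mbp was at log2 0.24 (adjusted p = 0.0124, 0.0569 without shTardbp 3, and 0.00253 to 0.296 over all alternatives). Fibroblast and mesenchyme markers had 5 higher and 5 lower of 24 (5 and 6 adjusted over the list alone; adjusted p = 0.794), with a median of 0.0222, a mean of -0.0444 and a test that pointed down. The matrix genes Dcn and Mmp2 fell 3.05-fold and 1.68-fold, and S100a4 rose 1.85-fold. Pdgfrb rose 1.33-fold against the mean of the controls, with adjusted p = 0.822 against shGFP alone. Muscle, epithelium and endothelium markers had 2 higher, Vwf (log2 0.70) and Pecam1 (0.41), and 0 lower of 14 (the same adjusted over the list alone; adjusted p = 0.346).

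The comparison of shGFP with shLuciferase gives the difference between control lines with no knockdown. Ramp3, which modifies receptors of the calcitonin family, was 3.46 higher in shGFP on the log2 scale (SE 0.142, adjusted p = 1.29e-08, n = 4 against 3). The thioredoxin inhibitor Txnip (2.30), Klhl4 (2.19, from a shLuciferase mean of 3.68, not shown to be above background) and the G protein signalling regulators Rgs4 (2.16) and Rgs5 (1.79) were higher as well. Phlda2 (log2 -2.02), the lipoprotein lipase gene Lpl (-1.57), the growth factor receptor Fgfr2 (-1.54), Apol9b (-1.35) and Mrfap1 (-1.44, 1 probe set) were lower in shGFP. Unfolded protein and integrated stress response genes were higher in shGFP, 21 of 36 with none lower (adjusted p = 2.88e-14; adjusted p = 0.0833 with an estimated correlation). This list was lower in shTardbp against shGFP (19 of 36 genes, adjusted p = 5.85e-05; adjusted p = 0.387 with an estimated correlation) and not against shLuciferase (9 higher and 3 lower, adjusted p = 0.276). Oxidative stress genes were lower in shGFP (4 of 24, 1 higher, adjusted p = 0.0439; adjusted p = 0.942 with an estimated correlation).

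In all 1752 genes differed between the controls, 990 higher and 762 lower in shGFP, 61 and 24 of them at least 2-fold. The count was 962 with the median of the probe sets, 2916 with array weights, 1000 with the replicate number as a block and 1604 without shLuciferase 4, of which 1314 were among the 1752. The call of Mrfap1 (adjusted p = 0.0175) was lost without shGFP 5 (0.0521), shLuciferase 1 (0.0705) or shLuciferase 4 (0.0697), and with the replicate number as a block (0.0601).

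Probe set usage asked whether parts of a gene changed differently from the rest. In Eps15, 1 probe set (ps5204428) fell by 3.58 on the log2 scale relative to the rest of the gene, from 9.04 ± 0.338 (SD, n = 4) in shGFP and 8.32 ± 0.154 (n = 3) in shLuciferase to 3.31 ± 0.0607 (n = 4) in shTardbp. The last value lies below the 25th percentile of every array (4.46 to 4.57), as does the shLuciferase mean of the Wiz probe set below (4.11), so neither is shown to be above background and the exact differences are not known. In Dscam, a neuronal adhesion molecule, ps4441079 fell by 2.71 relative to the rest, from 10.3 and 10.1 in the controls to 6.77. Cab39l (ps5017202, 2.56) and Wiz (ps4404633, 2.07) had a probe set that rose against the rest of the gene, and Nfia (ps4721865, -2.21) had a probe set that fell. In Gfra1 (ps5314328, 2.21), Gnb3 (ps5116539, -2.00), Tmem218 (ps4901571, 1.96) and Dmkn (ps5558701, -1.88) the probe set itself moved by 0.026, 0.034, 0.036 and 0.061, and the gene around it changed. In 1500015O10Rik (ps4605260, 2.11) the probe set changed by -0.50 and the gene by -1.68. All 10 also passed with a variance of their own, with adjusted p-values from 2.39e-07 to 0.00468.

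**Figure D4:**
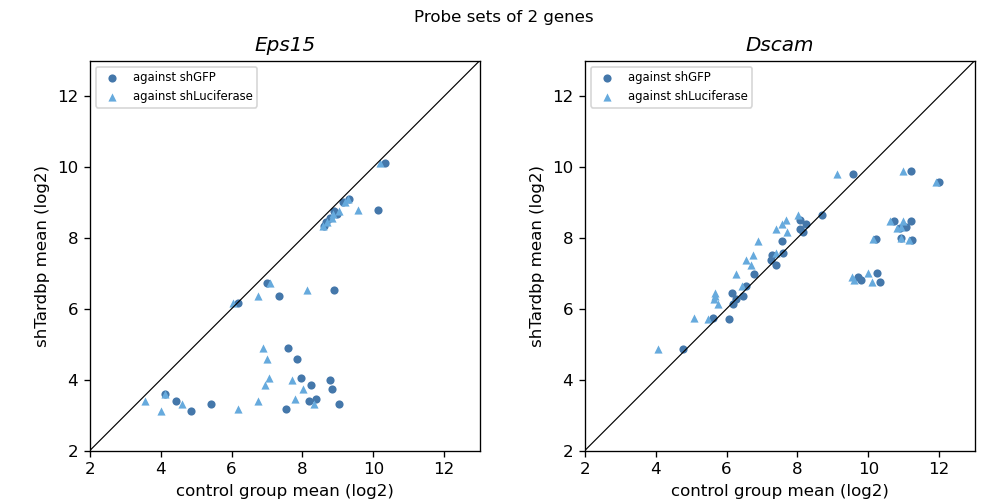
Mean log2 value of each probe set of Eps15 and Dscam in shTardbp (vertical) against its mean in shGFP (circles) and in shLuciferase (triangles), with the line of equal values. In each gene part of the probe sets lies near the line and another part far below it.

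In total 1968 of 101898 probe sets changed in usage, 956 higher and 1012 lower than the rest of their gene, in 1225 of 7531 genes (16.3%). With the array code letter as a block 1872 passed, with another balance of directions (1274 higher and 598 lower), in 1321 genes. Between the controls 430 probe sets and 365 genes passed. A variance of its own for each probe set gave 896 probe sets and 401 genes, 646 and 335 of them shared, and 48 probe sets in 47 genes between the controls. Of 3557 tested genes that changed in level 24.8% changed in usage, against 8.66% of the 3974 others, and 402 of the 1968 probe sets moved by under 0.2 themselves, 399 of them in genes whose level changed. Over 134 called probe sets in 53 genes that changed by at least 0.5 in level in this comparison and between the controls, the usage difference relative to the gene's change correlated between the comparisons (r = 0.837, rho = 0.808, across probe sets, which are not independent replicates). The comparisons share the control arrays, and rho was 0.635 to 0.809 over 36 divisions of the controls with no shared array.

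Among the TDP-43 splicing targets, Dclk1 (ps5100414, 0.71, adjusted p = 0.000171), Tbc1d1 (ps4721586, 0.75, 0.00297), Madd (ps4430847, 0.52, 0.00694) and Poldip3 (ps4478976, -0.38, 0.0325) had a probe set with changed usage, and Ahi1 (ps4494215, 0.39) had adjusted p = 0.142. With a variance of its own for each probe set none of these passed (0.137, 0.121, 0.138, 0.154 and 0.585), and with diffSplice Tbc1d1 was lost without shTardbp 2 (0.163), Madd without shTardbp 3 (0.112) and Poldip3 when shGFP 1 or 3, shLuciferase 4, or shTardbp 1, 2 or 3 was left out (0.0507 to 0.17), while Ahi1 passed without shTardbp 2 (0.0115). With the array code letter as a block Dclk1 (0.631), Tbc1d1 (0.0502), Madd (0.0718) and Poldip3 (0.0816) were lost. In that list 4 of 18 tested genes changed in usage (4 adjusted over the list alone; Fisher's exact test, adjusted p = 1). Cell cycle genes changed in usage in 16 of 46 (22 adjusted over the list alone; 34.8%, against 16.2% of other genes, Fisher's exact test, adjusted p = 0.039 over the 20 lists). Among genes that changed in level the shares were 16 of 41 against 24.6% (unadjusted p = 0.0438, a test chosen after the result was seen), and the count was 6 of 46 with a variance of its own for each probe set (unadjusted p = 0.0339). Splicing regulators stood at 16 of 64 (18 adjusted over the list alone; adjusted p = 0.608) and core spliceosome genes at 7 of 48 (7 adjusted over the list alone; adjusted p = 1).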

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

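The tests of the array code, of shLuciferase 4, of probe sets that moved less than their gene and of usage in genes of unchanged level were chosen after the result was seen. The test of probe set response was written before its own value was seen but after the usage counts, and its shuffles and divided controls were added after it.

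In 14 of 202 sets of 4 arrays tested for the named genes and array medians, 1 array stood far from the other 3, where chance gives about 1 in 20 sets, or 10.1. The gap to the nearest array, as a share of the whole range, was 0.91 for Apol9b and 0.869 for Mupcdh (both low in shTardbp 1), 0.901 for Lgi1 (high in shTardbp 2), 0.854 for Crem (low in shTardbp 1) and 0.951 for Astn2 (high in shTardbp 2). In shGFP it was 0.92 for Snrpa1 and 0.944 for Uqcrfs1 (both high in shGFP 2), 0.895 for Rbm10 (low in shGFP 5), 0.834 for Hspa1a (high in shGFP 5), and 0.866 for Chga, 0.929 for Bag3 and 0.911 for Hsd17b7 (all low in shGFP 1). S100a4 had a high value in shGFP 2 (0.84) and in shTardbp 2 (0.873).

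Probe sets with several gene names or none were outside the gene comparisons. Of 14797 such probe sets 1267 (8.56%) differed between shTardbp and both controls, 731 higher and 536 lower, and 307 (2.07%) differed between the controls.

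The first pattern is the large number of genes changed in shTardbp. A chance assignment of these arrays to groups is excluded for 4825 genes against both controls (highest of the other 99 relabellings of the arrays 53, 1 of 100 as large). The same holds for 2699 against each control (highest other 0, 1 of 100, which does not test whether these comparisons match). It also holds for 4416 against shGFP (highest other split 1, 1 of 35) and for 4120 against shLuciferase (highest other 172, 1 of 35). Chance differences between clones are not excluded, since the arrays of a group may come from a single clone. A difference that goes with the array code letter is not settled. Over genes changed against shGFP, the P array of shLuciferase minus its C arrays had a slope of -0.00199 on the knockdown change (-0.0241 to 0.0184 over random subsets of the genes). As the whole cause the letter needs a slope near 1, but this rests on 1 array and weighs large changes most. The median of that P minus C difference was 0.121 for synaptic and -0.143 for nuclear transport genes, near shTardbp minus shGFP (0.123 and -0.121). These were among the closest matches of the 20 lists. In some other lists the signs were opposite, such as autophagy and lysosome (-0.107, shTardbp minus shGFP 0.109) and oxidative stress response (-0.172, shTardbp minus shGFP 0.146). For cell cycle genes it was -0.0169 (shTardbp minus shGFP -0.555). With the letter as a block 2509 genes passed and the call of Tardbp was lost. Copy number differences between the stable lines may account for part of the changes: expressed genes 20 places apart along a chromosome had correlated changes (0.118, shuffled orders -0.0431 to 0.0463), and no DNA was measured here to settle it. An effect of Tardbp loss also stays open, as untested, since 1 hairpin was used against Tardbp.

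The second pattern is the difference between the controls, 1752 genes, for which a chance assignment of these arrays is excluded (highest other split 86, 1 of 35). A deviating shLuciferase 4 is argued against as its source, since 1604 genes, 1314 of them among the 1752, differed without that array (highest other split 0, 1 of 15). Changes of expressed genes 20 places apart also correlated here (0.0579, shuffled orders -0.0412 to 0.0421). Hairpin effects and differences between clones stay open, and no biological explanation was tested.

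The third pattern is usage. A chance assignment of these arrays is excluded for the counts of 1968 probe sets (highest other relabelling 364, 1 of 100) and 1225 genes (highest other 300, 1 of 100), although other relabellings gave a median of 44 genes. As above, chance differences between clones are not excluded. This holds for the counts and not for single calls, since 261 of the 459 calls of this test in the simulation were false. Probe sets that fail to follow their gene were looked for in the 950 level-changed genes with a called probe set. Of these genes 849 were among the 881 past the gene test. In 43.9% (40.7 to 47.1) of the 950 the top probe set moved less than its gene or the opposite way. This share cannot decide, since flat probe sets also dilute the gene's value and can make a probe set that follows the top call. Usage also changed in 344 genes whose level did not pass the threshold (8.66%, highest other relabelling 300 genes and 3.98%). This count cannot decide either, since a level change that flat probe sets dilute can miss the threshold. Probe sets that respond to a change in level to different degrees may account for some calls. Over 134 called probe sets in 53 genes the relative response correlated between the knockdown and the control comparison (r = 0.837, 0.780 to 0.881, at most 0.457 when shuffled within genes), which share the control arrays. It also correlated with no shared array (rho 0.635 to 0.809), though transcripts that vary together in both comparisons would give the same. The 134 are a small part of the 1968 calls, from genes that changed by at least 0.5 in both comparisons. The other calls were not tested in this way. The count of level-unchanged genes with changed usage was 65 with a variance of its own for each probe set, so that splicing changes remain a hypothesis for single genes.

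For the gene list tests, 8 of 20 lists passed and chance is not excluded: 22 of 100 relabellings gave as many, and the highest other gave 12. Taken singly, the medians of 7 lists exceeded those of every other relabelling, with no adjustment over the 20 lists: cell cycle (-0.55, highest other absolute median 0.359), TDP-43 splicing targets (0.146, 0.101), motor neuron markers (0.13, 0.107), synaptic genes (0.118, 0.107), cholesterol synthesis (-0.215, 0.167), autophagy and lysosome (0.191, 0.167) and nuclear transport (-0.151, 0.144).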

How the results depend on the processing

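The array code block, the regional correction, the usage test with a variance of its own for each probe set and the usage counts limited to some probe sets or genes were chosen after seeing the data; the other settings were fixed before. Over all settings, 1926 of 1971 values of 100 named gene results kept direction and side of the threshold (44 lost the call, 1 reversed), as did 415 of 439 list tests (16 lost, 7 gained, 1 reversed) and 245 of 263 named probe set values (17 lost, 1 gained). The cause was not tested unless stated. The median of the probe sets gave 962 genes between the controls and 1776 against each control, and array weights gave 2916 between the controls. With the array code letter as a block, where 1 control array shares its letter with shTardbp so that errors grow, there were 2509 genes against both controls, 1933 against shGFP, 1418 against each control and 2977 against shLuciferase, Tardbp was at -0.29 (adjusted p = 0.173), Hspa1a turned to -0.062 and the nuclear transport list turned (adjusted p = 0.978). A minimum change of 0.5 left 1345 genes, by construction, and an estimated correlation left 1 list. Usage counts were 1145 probe sets above the 50th percentile, 896 probe sets and 401 genes with a variance of its own for each probe set, and, fewer by construction, 1148 and 799 where the probe set's own level changed and 447 and 344 in genes of unchanged level.

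Leaving out 1 array at a time gave 4093 to 4984 genes against both controls, 3765 to 4710 against shGFP, 3361 to 4220 against shLuciferase, 1204 to 1743 between the controls, 2274 to 2654 against each control, Tardbp at -0.44 to -0.37, 7 to 9 lists, and 1380 to 2518 probe sets in 899 to 1570 genes for usage. The share of higher genes was 44.4% as deposited, 45.2% after quantile normalization and 43.9% after centring. The directions were nearly even with the array code letter as a block (1223 higher, 1286 lower) and with the regional shift subtracted (2248 and 2269). The regional correction centres each neighbourhood near no change, so its even balance follows in part from its construction. Subtracting the regional shift left 4517 genes, 3969 of them shared with the 4825, and ended the calls of Xbp1, Bag3 and Atp5o.

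Whether the replicate numbers pair the arrays is not settled. Deviations of same-numbered arrays correlated at 0.116, 0.201 and 0.201 between shGFP and shTardbp and at -0.0561 to 0.263 over all pairs (median of other pairs -0.0122), and 5 of 10 arrays correlated best with a same-numbered one. With the replicate number as a block there were 4699 genes against both controls, 3937 against shGFP, 3962 against shLuciferase, 1000 between the controls and 2473 against each control, and 2163 probe sets in 1390 genes for usage.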

Other observations

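The tests of symbol families, of parted probe sets and of windows of neighbouring genes in this part were chosen after the result was seen.

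Among 94 families of genes with a shared symbol root, the clustered protocadherins of the beta group, adhesion molecules of neurons, stood out. Of 22 measured Pcdhb genes 18 rose in shTardbp and 0 fell, with a median log2 change of 0.63 (adjusted p = 1.03e-09; adjusted p = 0.622 with an estimated correlation), for example Pcdhb3 (0.65) and Pcdhb2 (0.89). They were also higher in shGFP than in shLuciferase (median 0.35, adjusted p = 3.46e-06). Genes of the mitochondrial ribosome fell, 14 of 27 Mrps genes (median -0.28, adjusted p = 0.000125; adjusted p = 0.781 with an estimated correlation) and 20 of 41 Mrpl genes with 1 higher (-0.21, adjusted p = 0.000535; adjusted p = 0.842 with an estimated correlation). Of 28 Med genes of the Mediator complex 12 fell (median -0.145, adjusted p = 0.00402, and adjusted p = 0.781 with an estimated correlation). Their median in shGFP minus shLuciferase was nearly as low (-0.124, adjusted p = 0.0956). Of 47 genes with the symbol root Eif, which do not all share 1 function, 16 fell and 1 rose (adjusted p = 0.0139, and adjusted p = 0.781 with an estimated correlation). The Cdc (13 of 29 lower, 2 higher, adjusted p = 0.00851; adjusted p = 0.741 with an estimated correlation), Rad (9 of 15 lower, 1 higher, adjusted p = 0.013; adjusted p = 0.781 with an estimated correlation) and Nup families (8 of 17 lower, adjusted p = 0.0175; adjusted p = 0.781 with an estimated correlation) fell as well. Hist genes went the other way, 8 of 18 higher and 1 lower (median 0.199, adjusted p = 0.0237, and adjusted p = 0.781 with an estimated correlation). Their median in shGFP minus shLuciferase was 0.174 (adjusted p = 0.0699), while that of the Cdc and Rad families was 0.00767 and -0.00954.

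In Eps15 and Dscam some probe sets fell by at least 2 while others moved by under 0.5. In Eps15, 10 of 22 bright probe sets averaged 8.24 in shGFP, 7.27 in shLuciferase and 3.84 in shTardbp, while 9 others averaged 8.86, 8.86 and 8.64. In Dscam, 12 of 24 averaged 10.7, 10.6 and 7.88, while 7 others averaged 8.13, 7.58 and 8.17, so the part that fell was lower but not lost. The remaining probe sets of both genes were in neither part. No other gene had at least 4 bright probe sets that fell by 2 or more beside 4 that moved by under 0.5, and none did so between the controls. Probe set positions were not used here, so whether the part that fell lies at an end of the gene was not tested.

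Some stretches of neighbouring genes moved together in shTardbp. In a window of neighbouring expressed genes from Nmt2 to Tor1b, 92 were lower, 9 higher and 74 passed the threshold as lower, with a median log2 change of -0.34 and single arrays at -0.367 to -0.38. From Riok3 to Snx24, 88 were higher and 13 lower (median 0.31, single arrays 0.252 to 0.364). Shuffled gene orders gave window medians of -0.203 to 0.105, and shGFP and shLuciferase differed in these windows by -0.0102 and 0.027. Of the 6860 ordered expressed genes, 2545 lay in windows outside the shuffles (53.8% of them passed, against 43.3% of other ordered genes). They held 28.4% of all calls, a total that includes calls of genes that were not ordered. Such windows held 1071 genes between the controls, and 43 of the 100 named genes lie in the shTardbp windows, 18 in low ones. The share of all measured genes that lie in them was not computed, so the 43 are not shown to be more than usual. All 22 Pcdhb genes lie between Riok3 and Snx24, where 174 other measured genes had a median of 0.19.

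A candidate explanation is a gain or loss of chromosome parts in the cells that founded the shTardbp lines, shared by all 4 arrays, for which the correlation of genes 20 places apart (0.118) is the test; regulation of whole domains was not tested. Subtracting the running median over neighbouring genes left the cell cycle median at -0.58 (-0.55 before) and Tardbp at -0.40 (adjusted p = 0.00254). The cell cycle fall is thus not explained by the local shift around its genes alone. Whether shifted regions act on cell cycle genes elsewhere was not tested, since the correction removes only the local part. The correction removed a median of 0.0706 from a gene's log2 change, so that small changes are the most open to it.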
